A study of Mus musculus with 5 samples.

How the data were processed

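RNA of 5 cultures of proliferating C2C12 mouse myoblasts was measured, 1 library per condition. Per the labels' protocols, the hairpins were present for 72 h and the compounds or vehicle for 8 h, the cells grew in high-glucose medium with fetal bovine serum, polyadenylated RNA was isolated and made into libraries with NEBNext kits, and sequencing ran on a NextSeq500. The doses of shikonin and TEPP-46 and the hairpin sequences are not in the labels. Per the submitters' processing notes, reads were handled with Trim Galore 0.6.0, cutadapt and FastQC, DESeq2 1.26.0 was among the tools, and the genome build was GRCm38. The aligner, the program that made the expression values, the annotation and the use of strand are not given in the sources used here. The authors deposited 1 table of FPKM values, fragments per kilobase of gene and 1000000 mapped fragments, with 1 column per library. Every column was matched to a condition by its name. The name of the shControl column ends in a number, 30, that the labels do not explain, and all knockdown values rest on that column. FPKM values are already divided by a measure of library size and by gene length. They therefore do not give read counts directly, and a count model was not used. Median-of-ratios factors of the values were 0.9991 to 1.002. The measure of library size may thus be such a factor rather than the mapped fragments, and the depths given here are relative to it.

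Library depth was read from the lowest values. Within 3595 of 4737 low genes (75.9%), the values of all libraries were whole multiples of 1 step within a tolerance of 0.02. The most frequent ratio between libraries, found in 353 to 415 of the 2336 to 2435 low genes compared, gave the value of 1 read relative to the vehicle library: 1.19 in shPKM2, 1.35 in shControl, 1.38 in shikonin and 1.28 in TEPP-46. Using GENCODE M21 transcript lengths, 1124 genes with a single transcript gave a median depth of 31.7 times 1000000 reads for the vehicle library (quartiles 30.2 and 32.7), and the ratios gave the other depths. These depths are estimates. Symbols of 21725 genes matched the annotation directly and 1244 further genes matched through older symbols in the RefSeq gene table, so that 99.3% of the genes with a mean of at least 1 FPKM had a length. The counting SE of a difference was computed from the estimated reads of both libraries, for the log2 ratio without the added 1. For genes near or below 1 FPKM it is therefore larger than the counting error of the log2(FPKM + 1) difference beside it. It covers counting error only, and covers neither variation between cultures nor library preparation, so it leaves out part of the uncertainty of every difference. It is not valid for short RNAs, whose effective length is unknown.

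Values were transformed as log2(FPKM + 1), and a difference is that of 1 library minus another. Genes entered with a mean of at least 1 FPKM over all 5 libraries. The comparisons were shPKM2 against shControl, shikonin against vehicle, TEPP-46 against vehicle, shikonin against TEPP-46, and shControl against vehicle as a yardstick. With 1 library per condition no test was made, and genes were counted by size, at least 2-fold in either direction. Noise from counting was simulated by drawing Poisson reads for both libraries around the same level, 20 times. Of 42 gene lists fixed before the data were examined, 34 had at least 5 measured genes. For these the median difference was given with its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. A list was said to stand apart below percentile 2.5 or above 97.5. About 1.7 of 34 lists do so by chance, and more may since random lists ignore that genes of a pathway move together. Lists share members, so they are not independent.

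The genes named were fixed by rule before the data were examined: the 12 highest and 12 lowest of each main comparison and the 6 highest and 6 lowest between the compounds, with a mean of at least 5 FPKM and leaving out gene models without a regular symbol; up to 10 genes each way that differed at least 2-fold in all 3 main comparisons; up to 4 members of each list in each comparison; and Pkm and Pklr. Other list members are named where a group is described. Many places of the rule went to microRNA and small nucleolar RNA genes, which polyadenylated libraries cover poorly and whose FPKM jumps from 0 with 1 read, such as Snord104, Mir3074-1 and Snord1c in the knockdown, Mir3064 and Snord83b with shikonin, and Snord23 and Mir25 with TEPP-46. After the values were seen, the same numbers of genes were therefore also taken among longer genes, leaving out the 80 genes under 300 nt or of these classes, and these are the ones described. Rn45s, Rmrp, Rpph1 and Lars2 were also looked at together after the values were seen. They differed in the same direction as each other within every comparison. Since polyadenylated RNA was isolated, their values may depend on how much other RNA was carried over. This was not tested, so their differences are not read as responses of the cells.

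The medians and means of a list differed in sign for pentose phosphate genes with shikonin (median -0.09, mean 0.16) and between the compounds (-0.21 and 0.08), core histones with shikonin (-0.12 and 0.08) and between the compounds (-0.20 and 0.03), immediate early genes with TEPP-46 (-0.04 and 0.10) and between the control libraries (-0.01 and 0.07), YAP targets in the knockdown (0.01 and -0.08), splicing factors with TEPP-46 (0.02 and -0.04), heat shock genes between the control libraries (-0.06 and 0.02) and fatty acid synthesis genes between the compounds (0.05 and -0.01). The lists for Wnt targets, fatty acid synthesis and splicing factors stood apart in none of the 3 main comparisons, with medians of -0.05, 0.03 and -0.04 in the knockdown.

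The alternatives were pseudocounts of 0.1 and 5, no filter on low genes, a minimum mean of 5 FPKM, rescaling each library to TPM, median-of-ratios scaling, size limits of 1.5-fold and 3-fold, the control library of the other experiment, and random lists without matching. Leaving out short RNA genes was added after seeing the data. The steps were tested on simulated reads for 10972 genes at the estimated depths. With 50 genes planted at each fold size in the knockdown comparison, 90% of genes changed 3-fold, 82% of those changed 2.5-fold and 0% of those changed 1.5-fold were counted as at least 2-fold in the planted direction, and 0 unchanged genes were counted. Of 200 random lists, 3.5% fell outside the percentile limits, and 20 of 20 lists of 30 genes raised 1.2-fold were found above them. The first share is largely set by the limits, because those lists came from the same genes as their comparison lists. The simulated reads held counting error only, without variation between cultures or library preparation, so real libraries would give less favourable rates. For the compounds, a planted covariance of 0.0500 was recovered as 0.0494. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.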

Results

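C2C12 cells, an immortalised mouse myoblast line that stands in for muscle progenitors, were profiled by sequencing of polyadenylated RNA while they were proliferating. The 5 libraries comprised cells carrying a short hairpin RNA against PKM2 (shPKM2) and cells carrying a control hairpin (shControl), both for 72 h, and cells given vehicle, shikonin or TEPP-46 for 8 h. PKM2 is the M2 splice form of pyruvate kinase, the enzyme of the last step of glycolysis. Shikonin is a plant naphthoquinone used as a PKM2 inhibitor, and TEPP-46 is a small molecule known as a PKM2 activator. The title of the series speaks of inhibiting PKM2 by small molecules and genetically, which does not match TEPP-46 as an activator, and the labels do not explain this. Each condition had 1 library, so no difference given here has a replicate check, no p-value was computed, and every value describes these libraries. Of the 23361 genes in the table, 11128 had a mean of at least 1 FPKM (fragments per kilobase, scaled to library size) over the 5 libraries. The depth, estimated from the steps of the lowest values, in units of 1000000 reads, was 26.7 for shPKM2, 23.5 for shControl, 31.7 for vehicle, 22.9 for shikonin and 24.8 for TEPP-46. Differences are on the log2(FPKM + 1) scale, which understates those of low genes. The errors beside them are standard errors (SE) from counting alone, computed without the added 1 and therefore too large for low genes.

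Pkm, the gene that encodes PKM2 and lies on chromosome 9 (59656368 to 59679375, plus strand, GRCm38), stood at 1041 FPKM in the shPKM2 library and at 2061 FPKM in the shControl library. The shPKM2 level was 0.505 times the shControl level, a difference of -0.98 (counting SE 0.0073). In the 8 h libraries Pkm stood at 1321 FPKM with vehicle, 1501 FPKM with shikonin and 1198 FPKM with TEPP-46, differences from vehicle of 0.18 and -0.14. The shControl library held more Pkm than the vehicle library, by 0.64, so the shPKM2 level lay closer to the vehicle level than to that of its own control. Pklr, the liver and red cell pyruvate kinase gene on chromosome 3, was listed at 0 in all 5 libraries. A value per gene sums the M1 and M2 forms of Pkm and does not separate them.

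**Figure D1:**
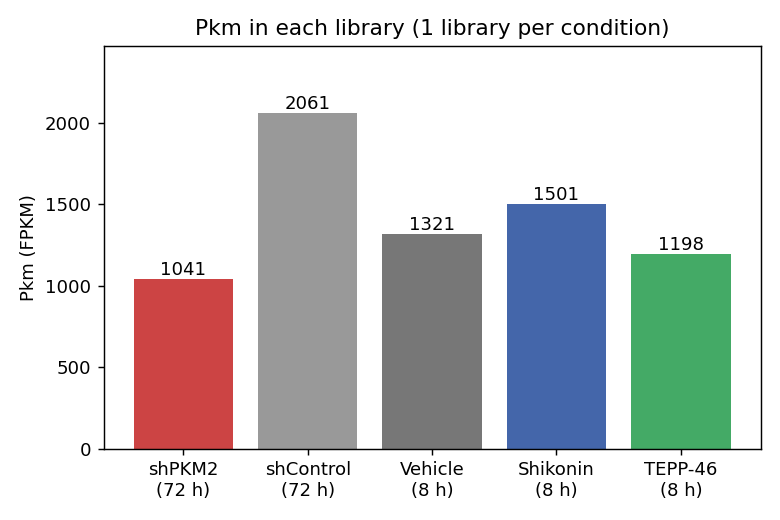
Pkm expression in FPKM in each of the 5 libraries, 1 bar per library with no error bar because each condition has 1 library. The shPKM2 bar stands at 1041 and the shControl bar at 2061, and the 3 libraries of 8 h lie between 1198 and 1501.

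The comparison of shPKM2 with shControl asked what lowering Pkm for 72 h did to the transcriptome. Glutathione S-transferase genes and Hmox1 were among the highest in the shPKM2 library. Gsta2 was higher by 2.44 (counting SE 0.16), Gsta1 by 1.82 and Gsta4 by 1.35. Hmox1, which encodes the haem-degrading enzyme heme oxygenase 1, stood at 218 FPKM against 74.4 FPKM, a difference of 1.54 (counting SE 0.031). Gsta1 and Gsta2 are near-identical copies, so the split of reads between them is uncertain. Nqo1, a quinone reductase gene, was higher by 1.01, and Aldh3a1, an aldehyde dehydrogenase gene, by 1.13. Of the 29 measured NRF2 targets (genes driven by the oxidant-responsive factor NRF2), 25 were higher and 6 were at least 2-fold higher. Their median difference of 0.49 lay at percentile 100 of 10000 random lists matched on expression. Among these members Gclm was higher by 0.77, Gclc by 0.69, Slc7a11 by 0.68 and Srxn1 by 0.57. Between the control libraries the list stood apart on the low side in shControl (median -0.15, percentile 0.36). There 17 of the 29 were lower in shControl than in vehicle and 12 higher. Among them were Txnrd1 (-1.01), Gsta4 (-0.95), Srxn1 (-0.93) and, on the high side, Mgst1 (1.33). With vehicle as the control of shPKM2 the list median was 0.27 and still stood apart (percentile 99.99).

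Other genes among the highest in the shPKM2 library were Mmp10, a matrix metalloproteinase gene (1.67), Prr9 (1.64), the carbonic anhydrase gene Car3 (1.62), Cd68 (1.32), Gpnmb (1.29), Amd1 (1.17) and Trim54 (1.12). At the low end stood Vgll2, a cofactor of TEAD factors in muscle (-1.29, counting SE 0.094), the chemokine gene Ccl5 (-1.26), Plac8 (-1.19), Tmsb4x (-1.17), which encodes thymosin beta 4, and Ctgf (-1.11), a connective tissue growth factor gene. They were followed by Eif3j2 (-1.08), Rps27 (-1.06), Snx18 (-1.02), the collagen crosslinking gene Loxl2 (4.44 FPKM against 9.87 FPKM), Pkm itself (-0.98), Socs2 (-0.87) and Cck (-0.85). Amd1, Eif3j2 and Rps27 have closely similar copies in the genome, and their values are uncertain for that reason.

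Muscle and matrix genes differed by less. The 26 measured genes of myogenic differentiation had a median of 0.26 (percentile 100), with Acta1 at 0.61, Myl1 at 0.56, Casq2 at 0.55 and Chrnd at 0.55, while Myog, the myogenin gene, was at -0.55. Myoblast identity genes were within the range of random lists (median -0.07, percentile 5.61), with Cdh15 at -0.49, Hes1 at -0.46 and Myf5 at -0.46. The extracellular matrix list was lower (median -0.18, percentile 0), led by Loxl2, Dcn (-0.89), Tnc (-0.68) and Fn1 (-0.64). NF-kB and inflammatory genes had a median of -0.26 (percentile 0), with Ccl2 at -0.82 beside Ccl5, and hypoxia targets of HIF1 one of -0.19 (percentile 0.01), with Bnip3 at -0.76, Ddit4 at -0.60 and Car9 at -0.44, but Pfkfb4 at 0.68. The 8 measured core histone genes were all lower (median -0.32, percentile 0). Further medians that stood apart were those of G2/M genes (-0.10), immediate early genes (-0.12), TGF-beta targets (-0.11), heat shock genes (0.07), serine, glycine and one-carbon genes (0.07), ribosome biogenesis genes (0.05), autophagy and lysosome genes (0.10), ubiquitin and atrophy genes (0.11) and the metal response list (0.23), which shares Hmox1, Fth1 and Ftl1 with the NRF2 list. Serine, glycine and one-carbon, heat shock and ribosome biogenesis genes did not stand apart from random lists drawn without matching. Ubiquitin and atrophy genes did not with a minimum mean of 5 FPKM, and TGF-beta targets did not after rescaling to TPM (transcripts per 1000000). Neither ubiquitin and atrophy genes (percentile 97.03) nor TGF-beta targets (percentile 2.69) stood apart with no filter on low genes. With vehicle as the control instead, inflammatory genes (1.08), HIF1 targets (0.62) and ribosome biogenesis genes (-0.37) lay in the opposite direction, as did serine, glycine and one-carbon genes (-0.22). Myogenic differentiation (0.04), G2/M (-0.13), core histone (-0.04), immediate early (-0.11), heat shock (0.07) and ubiquitin and atrophy genes (0.15) did not stand apart with that control.

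Glycolysis genes, the pathway of PKM2, did not stand apart between shPKM2 and shControl: the median of 20 genes was -0.06 (percentile 24.8). With vehicle as the control it was 0.61. The lactate carrier genes Slc16a1 and Slc16a3 stood at 0.57 and -0.52, Pgam2 at 0.48 and Pfkl at -0.31. Medians of the pentose phosphate (0.04), TCA cycle (0.00), oxidative phosphorylation (-0.08) and amino acid (0.05) lists were also within the range of random lists, though Pgd was at 0.42, Pdk1 at -0.71 and Glul at 0.42. Oxidative phosphorylation genes did stand apart from unmatched random lists (percentile 0.55), and amino acid genes with a minimum mean of 5 FPKM (median 0.11, percentile 99.8). Integrated stress response genes did so too with that minimum (median 0.05, percentile 98.8). All 21 SRF and cytoskeleton genes were lower, with a median within the random range (-0.12, percentile 3.3). They stood apart from unmatched random lists (percentile 0.265) and with vehicle as the control (-0.50). With vehicle as the control, oxidative phosphorylation (0.16) and TCA cycle genes (0.15) stood apart on the high side. In all, 44 genes were at least 2-fold higher and 25 at least 2-fold lower in shPKM2 than in shControl. Without short RNA genes, whose values rest on few reads and are often listed at 0 in one of the libraries, the counts were 25 and 12. The RNA genes Rpph1 (0.84), Rmrp (0.26) and Rn45s (0.13) and Lars2 (0.32) were higher in shPKM2. A pseudocount of 5 gave 28 and 16, and vehicle as the control gave 456 and 91. Counting noise alone gave a mean of 0.15 genes in each direction in 20 simulations of 11051 genes. For short RNA genes, 19 of those higher and 13 of those lower, the simulation is not valid because their effective length is unknown. Among longer genes it gave a mean of 0. It leaves out variation between cultures and library preparation, so it is no measure of how many genes differ without a knockdown. Of 34 lists, 15 stood apart. Chance gives 1.7 for unrelated genes, and may give more where genes of a list move together. Between the control libraries 15 lists stood above the random range and 8 below it, so the number is not read as an effect of the knockdown.

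Shikonin was compared with vehicle at 8 h to see the response to a compound used against PKM2. The heat shock genes Hspa1a and Hspa1b, a near-identical pair encoding the inducible chaperone HSP70, were the highest of the longer genes. Hspa1a stood at 100.3 FPKM against 1.06 FPKM (5.62, counting SE 0.15) and Hspa1b at 383 FPKM against 12.8 FPKM (4.80). The small heat shock gene Cryab was higher by 3.07 and Hsph1 by 2.51. Of 22 heat shock genes, 21 were higher and 12 at least 2-fold (median 1.06, percentile 100). NRF2 targets were also higher, 16 of 29 at least 2-fold and 28 of 29 in direction (median 1.09, percentile 100). Hmox1 reached 1361 FPKM from 56.9 FPKM (4.56, counting SE 0.028), Osgin1 was higher by 3.57, Slc7a11 by 2.58 and Sqstm1, the autophagy receptor gene p62, by 3.32. All 31 proteasome subunit genes were higher, 10 of them at least 2-fold (median 0.85, percentile 100), led by Psma5 (1.33) and Psmd4 (1.32).

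Stress and damage lists followed in the shikonin library. Integrated stress response genes had a median of 0.84 (25 of 26 higher, 11 at least 2-fold, percentile 100), with the cytokine gene Gdf15 at 3.08, the phosphatase subunit gene Ppp1r15a at 2.93 and Ddit3, which encodes the factor CHOP, at 2.75. The unfolded protein response list stood at 0.55 (21 of 21 higher), with Dnajb9 at 2.00 and the chaperone gene Hspa5 at 1.79. Targets of p53 stood at 0.66, with Gadd45a at 2.77, Trp53inp1 at 2.65 and Mdm2 at 1.73. Autophagy and lysosome genes had a median of 0.75, with Gabarapl1 at 1.98 and the cathepsin gene Ctsd at 1.62. Inflammatory genes had a median of 0.46, with Ptgs2 at 2.87, Il6 at 1.78, Cxcl1 at 1.69 and Ccl2 at 1.53. Lists of metal response (0.61), ubiquitin and atrophy (0.60), HIF1 (0.29), immediate early (0.27) and interferon-stimulated genes (0.22) also stood apart on the high side. Further genes among the highest were Procr (3.84), Zfand2a (3.35), Calr3 (3.19), Mocos (3.06) and Nppb (2.98).

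Cell cycle genes were lower in the shikonin library as a group. All 32 G2/M and mitosis genes were lower and 29 at least 2-fold (median -1.40, quartiles -1.57 and -1.24, percentile 0). Ccna2, the cyclin A2 gene, stood at 30.04 FPKM against 111.6 FPKM (-1.86, counting SE 0.038), and Birc5 and Ccnb2 were both at -1.85. All 30 genes of G1/S and DNA replication were lower, 13 at least 2-fold (median -0.94), with the thymidine kinase gene Tk1 at -1.87, Rrm2 at -1.44 and Uhrf1 at -1.44. The kinetochore gene Nuf2 (-1.86) and Fam64a (-1.92), outside the lists, lay in the same range.

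Muscle and matrix genes were lower as well. Myog was at 0.278 FPKM against 5.30 FPKM, a difference of -2.30. Its counting SE of 0.48 is that of the log2 ratio without the added 1 and is too large for this difference. The median of myogenic differentiation was -0.62 (percentile 0), with Acta1 at -1.06 and Tnnc2 at -1.05. Myoblast identity genes had a median of -0.57 (percentile 0.01), with Myf5 at -1.32, Myod1 at -1.25 and Id3 at -1.15. Ctgf had the lowest difference of any longer named gene, 13.6 FPKM against 118 FPKM (-3.02, counting SE 0.054). Extracellular matrix genes had a median of -0.59, with Col3a1 at -1.82, Lox at -1.74 and Tnc at -1.68, and SRF and cytoskeleton genes one of -0.57, with Fhl1 at -1.60. TGF-beta targets (-0.48), YAP targets (-0.39) and TCA cycle genes (-0.32, with Idh2 at -1.39) also stood apart on the low side. Prss23 (-2.14), Krt80 (-2.05), the urokinase gene Plau (-1.98), Syt13 (-1.96) and Alox5 (-1.90) completed the low end.

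Glycolysis genes did not stand apart with shikonin (median 0.04, percentile 71.0), and no member reached 2-fold, Eno3 (-0.98) and Ldha (-0.80) being the lowest and Slc2a1 (0.71) the highest. In the pentose phosphate list Taldo1 (1.54) and Pgd (1.34) were at least 2-fold higher while the median was -0.09. Amino acid genes had a median of 0.16 within the random range, with Slc3a2 at 1.89 and Glul at 1.32. The RNA genes Rpph1 (7.06 FPKM against 3.02 FPKM), Rmrp (0.71) and Rn45s (0.48), the last a ribosomal precursor, were higher too, as was Lars2 (0.80). In all, 446 genes were at least 2-fold higher and 389 at least 2-fold lower, and 22 of 34 lists stood apart. The counts were 471 and 553 after rescaling to TPM, 244 and 168 with a pseudocount of 5, and the count of lower genes was 587 with a pseudocount of 0.1 and 831 with shControl as the control. With that control, inflammatory (-1.09) and interferon-stimulated genes (-3.99) lay in the opposite direction, glycolysis genes stood at -0.59, and the unfolded protein response (0.20), autophagy (0.17), immediate early (0.11), HIF1 (-0.16), TGF-beta (-0.03), YAP (0.10) and SRF (-0.11) lists did not stand apart. With a pseudocount of 5 the TCA cycle (-0.22) and interferon-stimulated (0.07) lists did not either. The TCA cycle list also did not with a minimum mean of 5 FPKM (-0.29, percentile 2.76).

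TEPP-46 was compared with the same vehicle library to see the response to a PKM2 activator. The metallothionein genes Mt2 and Mt1, which encode metal-binding proteins, were at 9511 FPKM against 615 FPKM (3.95, counting SE 0.016) and at 5452 FPKM against 543 FPKM (3.33). The zinc exporter gene Slc30a1 was higher by 2.10 and the zinc importer gene Slc39a10 had the lowest difference of the longer named genes (-1.94, counting SE 0.084). With shikonin these genes differed the same way and by less, Mt2 at 1.90, Mt1 at 1.81, Slc30a1 at 1.08 and Slc39a10 at -0.64. The whole metal response list did not follow these genes: its median was 0.61 with shikonin and 0.35 with TEPP-46, and 6 of 9 members were higher with shikonin than with TEPP-46.

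All 26 integrated stress response genes were higher with TEPP-46 and 17 were at least 2-fold higher (median 1.59, percentile 100). Trib3, a pseudokinase gene, was higher by 3.49, Ddit3 by 3.07 (243 FPKM against 28.02 FPKM), Chac1, a glutathione-degrading enzyme gene, by 2.74 and Atf3 by 2.67. Serine, glycine and one-carbon genes had a median of 0.59 (8 of 12 higher, percentile 100), with Aldh1l2 at 1.80, the transporter gene Slc1a4 at 1.45, Psph at 1.16 and Mthfd2 at 1.06. Amino acid genes stood at 0.31 (percentile 100), with Gpt2 at 1.70, Slc3a2 at 1.18 and Slc7a5 at 1.17. The NRF2 list stood at 0.35 (percentile 100) with Hmox1 at 2.30, Slc7a11 at 1.81 and Sqstm1 at 1.72. It shares Trib3 and Slc7a11 with the integrated stress response list. Unfolded protein response genes stayed within the random range (median 0.02), though Herpud1 was at 1.77 and Hspa5 at 1.13. Further genes at the high end were Car6 (3.59), Acot2 (2.61), Gadd45a (2.55), Ndrg1 (2.49), Adm2 (2.39) and the cystathionine lyase gene Cth (2.37). HIF1 targets stood apart (median 0.12, percentile 98.2), with 11 of 18 higher and 7 lower. Ndrg1, Ddit4 (1.97), Vegfa (1.39) and Ero1l (1.15) were at least 2-fold higher, and 1 member was at least 2-fold lower. The list did not stand apart after rescaling each library to TPM (percentile 96.1), with a pseudocount of 5 (median 0.05, percentile 90.3) or against unmatched random lists (percentile 97.1).

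Cell cycle genes were lower with TEPP-46 by smaller amounts than with shikonin. All 32 G2/M genes were lower, none of them by 2-fold (median -0.22, percentile 0), with Cdc20 and Cenpa at -0.48, and 27 of 30 G1/S genes were lower (median -0.36, percentile 0), with Ccne1 at -0.90 and Tk1 at -0.86. Heat shock genes had a median of -0.19 (percentile 0.09), led by Hspa8 at -0.81, and proteasome genes one of -0.14 (percentile 1.25). Cholesterol biosynthesis genes stood at -0.20 (percentile 0) and apoptosis regulators at -0.17 (percentile 0.5). Myoblast identity (-0.19), extracellular matrix (-0.12), TGF-beta (-0.21) and SRF (-0.20) genes stood apart on the low side, although Myf5 was higher by 1.07. On the high side stood autophagy and lysosome genes (0.16), ubiquitin and atrophy genes (0.23) and the metal response list (0.35). At the low end were Ccl2 (-1.67), Rgs16 (-1.51), Apln (-1.41), Ctgf (-1.36), Irs1 (-1.35), Cxcl12 (-1.34), Thbs1 (-1.33), Pdk4 (-1.31), Errfi1 (-1.25) and Serpinb2 (-1.15). Lars2 was at -1.36. The ribosomal precursor Rn45s stood at 249 FPKM with TEPP-46 and 512 FPKM with vehicle, and the RNA gene Rmrp at 3.73 FPKM and 11.3 FPKM. Whether these differences come from the cells or from library preparation was not tested.

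Glycolysis genes did not stand apart with TEPP-46 (median -0.09, percentile 17.6); Hk2, a hexokinase gene, was the highest at 0.81 and Slc2a1 was at 0.48. Myogenic differentiation genes (median 0.06), p53 targets (0.07), inflammatory genes (-0.09) and interferon-stimulated genes (0.03) were within the random range. In all, 137 genes were at least 2-fold higher and 40 at least 2-fold lower, and 18 of 34 lists stood apart. Without short RNA genes the counts were 130 and 25, a pseudocount of 0.1 gave 90 lower genes, a pseudocount of 5 gave 77 higher and 20 lower, and rescaling to TPM gave 153 higher and 61 lower. With shControl as the control 224 genes were higher and 488 lower, autophagy (-0.44), HIF1 (-0.56), extracellular matrix (0.25), TGF-beta (0.28) and SRF (0.24) genes lay in the opposite direction, and heat shock (-0.09), proteasome (-0.17) and ubiquitin genes (0.11) did not stand apart. Glycolysis genes stood at -0.86 and inflammatory genes at -1.08 with that control, and the extracellular matrix list did not stand apart without a filter on low genes (-0.08).

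**Figure D2:**
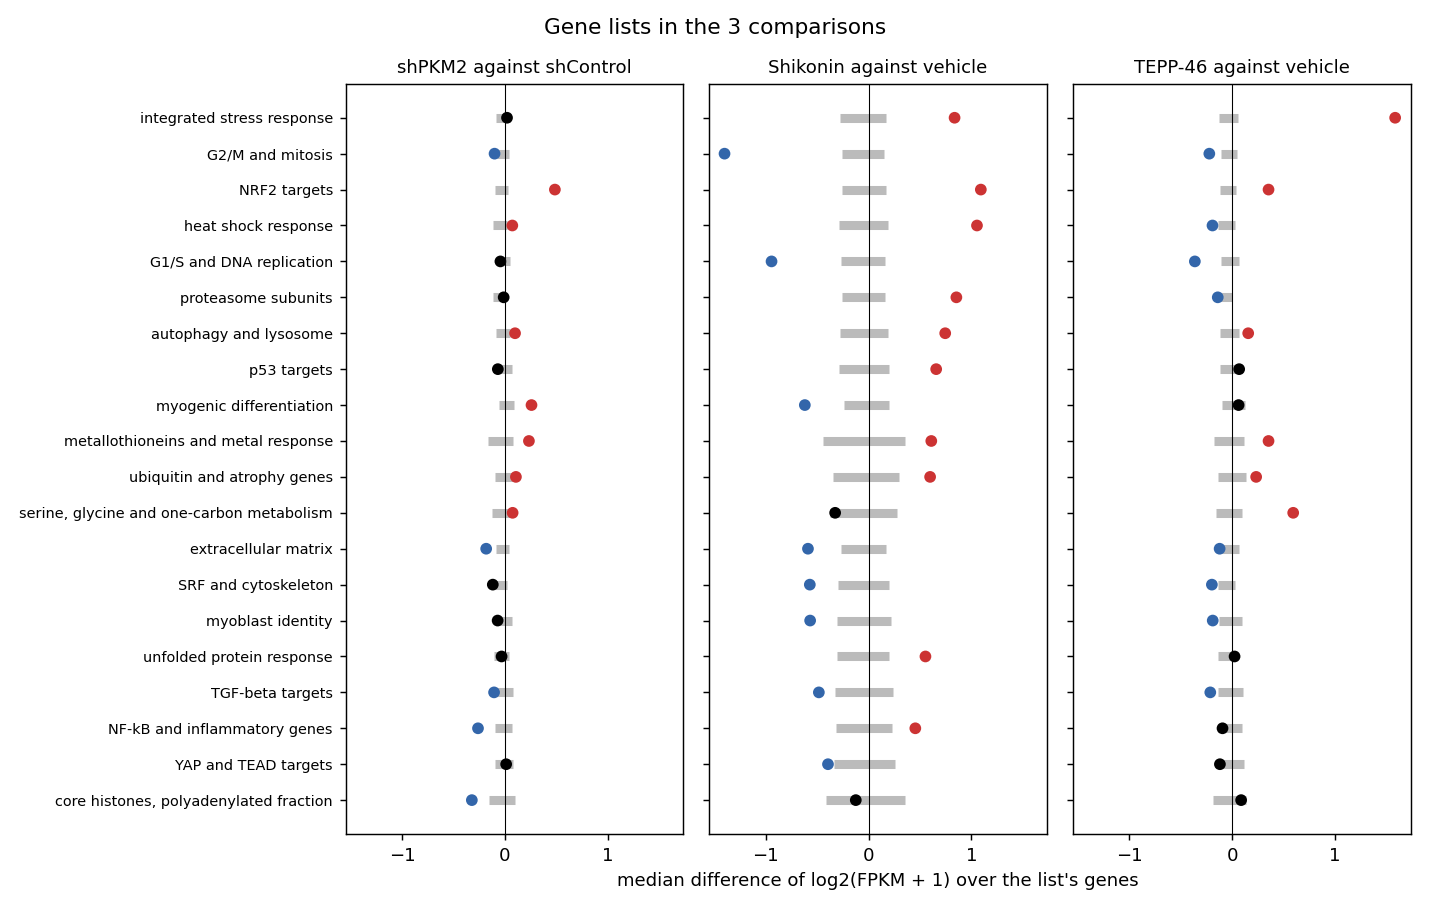
Median difference of log2(FPKM + 1) over the genes of each list (x axis) for the 20 lists with the largest medians that stood apart, in shPKM2 against shControl, shikonin against vehicle and TEPP-46 against vehicle, with 1 library per condition. Grey bars span the range of 10000 random lists without the outermost 2.5% at each end, and points are red above that range, blue below it and black within it; the G2/M list lies at -1.40 with shikonin and the integrated stress response list at 1.59 with TEPP-46.

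The compounds were also compared with each other at 8 h. Their doses are not in the labels, so they are not known to be matched. Hspa1a (5.85), Hspa1b (5.29), Procr (4.06), Calr3 (3.71), Cryab (3.27) and Ccl2 (3.19) were the highest of the longer genes with shikonin relative to TEPP-46, and Myf5 (-2.39), G0s2 (-2.21), Cth (-2.15), Fam64a (-2.14), H1f0 (-2.10) and Snai2 (-2.09) the lowest. By list, heat shock (1.11), proteasome (1.02), NRF2 (0.62), p53 (0.61), autophagy (0.49), inflammatory (0.45) and unfolded protein response (0.43) genes were higher with shikonin. G2/M (-1.15), serine, glycine and one-carbon (-0.80), integrated stress response (-0.56), myogenic differentiation (-0.54), SRF (-0.54), G1/S (-0.52) and extracellular matrix (-0.45) genes were higher with TEPP-46. In all, 405 genes were at least 2-fold higher and 405 at least 2-fold lower with shikonin than with TEPP-46, or 220 and 143 with a pseudocount of 5, 571 and 624 with a pseudocount of 0.1, and 439 and 582 after rescaling to TPM. Lars2 (2.15), Rmrp (2.09), Rpph1 (1.88) and Rn45s (1.51) were also higher with shikonin.

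Across 11128 genes, which are not independent replicates, the differences of shikonin and TEPP-46 from vehicle had a Pearson r of 0.337 and a Spearman rho of 0.274. Both use the same vehicle library, and unchanged libraries simulated against a shared control gave an r of 0.430 from counting noise. The covariance was 0.0738, against 0.00258 in that simulation, a difference of 0.0712. The simulated noise leaves out variation between cultures, so part of the excess may come from the single shared control. With shikonin compared to shControl instead the r was 0.185, and with TEPP-46 compared to shControl it was 0.0466. At least 2-fold higher with both compounds were 49 genes (5.49 for independent lists). At least 2-fold lower with both were 18 genes (1.40 for independent lists), or 9 without short RNA genes (0.86 for independent lists). Unchanged libraries simulated against the shared control gave a mean of 0.05 higher and 0 lower from counting noise. That simulation is not valid for short RNA genes, whose effective length is unknown. Some of the shared lower genes, such as Snord83b and Mir25, were short and listed at 0 with both compounds. Few reads in the shared vehicle library could give such drops. With shikonin compared to shControl the shared counts were 37 higher (6.16 for independent lists) and 9 lower (2.99), and with TEPP-46 compared to shControl 40 higher (8.98) and 36 lower (17.1). The knockdown and shikonin differences had an r of 0.133 and a rho of 0.188. Of their genes, 14 were at least 2-fold higher in both (1.76 for independent lists), 3 lower in both (0.87) and 4 at least 2-fold in opposite directions. Without short RNA genes the r was 0.209, with 9 higher and 2 lower in both. The knockdown and TEPP-46 differences had an r of 0.0333 and a rho of 0.0656. Of their genes, 3 were higher in both (0.54 for independent lists), 3 lower in both (0.09) and 5 at least 2-fold in opposite directions. Without short RNA genes the r was 0.0533, with 2 higher and 1 lower in both.

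**Figure D3:**
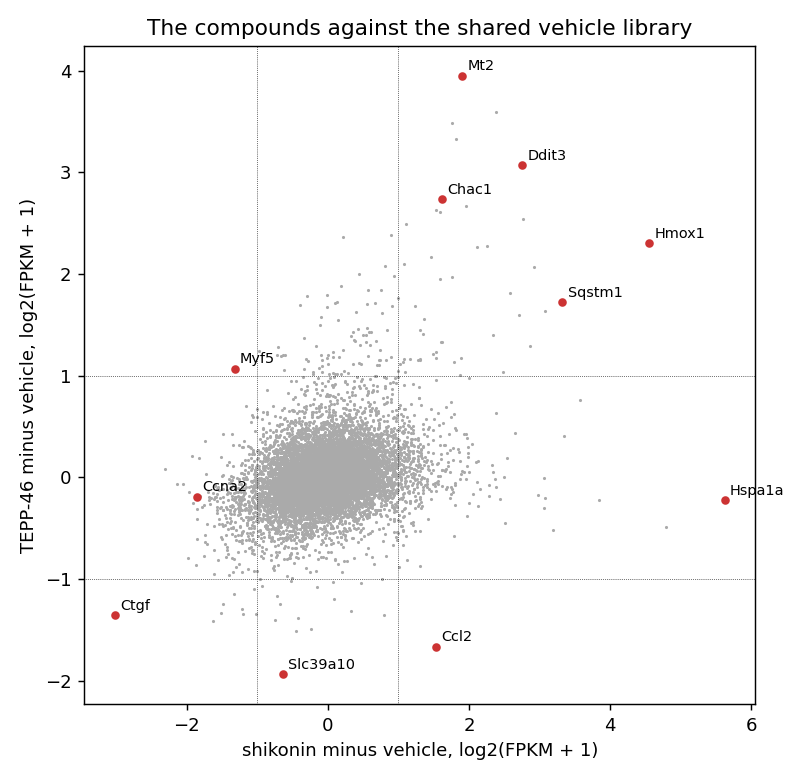
Difference from vehicle on the log2(FPKM + 1) scale with shikonin (x axis) and TEPP-46 (y axis), 1 point per gene with a mean of at least 1 FPKM, leaving out short RNA genes, from 1 library per condition. Dotted lines mark 2-fold; Hmox1 lies at 4.56 and 2.30, Hspa1a at 5.62 and -0.23, and Ccl2 at 1.53 and -1.67.

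Hmox1 and the small nucleolar RNA gene Snora68 were at least 2-fold higher in all 3 comparisons, and Ctgf and the microRNA gene Mir682 were at least 2-fold lower in all 3. Hmox1 differed by 1.54 in the knockdown, 4.56 with shikonin and 2.30 with TEPP-46, and Ctgf by -1.11, -3.02 and -1.36. Ctgf was far from equal in the controls, at 25.2 FPKM in shControl and 118 FPKM in vehicle, and its level with TEPP-46 (45.3 FPKM) lay above shControl, so the shared direction depends on the vehicle library. Snora68 differed by 1.35, 2.24 and 1.68. Mir682 was listed at 0 in the shPKM2, shikonin and TEPP-46 libraries, and its values rest on few reads.

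**Figure D4:**
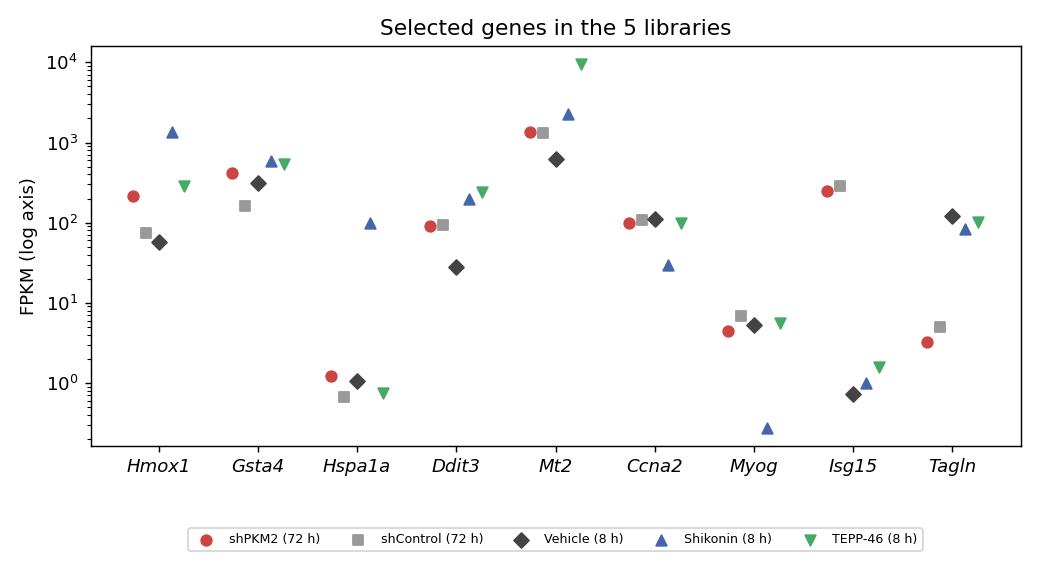
FPKM on a log axis of 9 genes in the 5 libraries, 1 point per library. Hmox1 is at 218, 1361 and 285 in the shPKM2, shikonin and TEPP-46 libraries against 74.4 in shControl and 56.9 in vehicle, and Isg15 is at 250.1 and 289 in the 72 h libraries and at most 1.59 in the 8 h libraries, while Tagln is lower in the 72 h libraries.

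The control libraries, shControl at 72 h and vehicle at 8 h, show how far apart libraries not aimed at PKM2 lay, although they also differ in vector and hours. Between them 387 genes were at least 2-fold higher and 74 at least 2-fold lower in shControl, more than between shPKM2 and shControl in both directions. Interferon-stimulated genes made the largest difference of any list: 31 of 31 were at least 2-fold higher in shControl (median 4.16), with Isg15 at 7.39 and Ifit1 at 6.33. The same list had a median of 0.01 between shPKM2 and shControl.

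Markers of other cell types were mostly near 0, and their lists had too few measured genes for a median. Among macrophage and blood markers Cd14 reached 26.7 FPKM, Hba-a1 12.3 FPKM and Cd68 12.9 FPKM, while Ptprc, Csf1r and Lyz2 stayed below 1 FPKM in every library. Cd68 was higher by 1.32 in the shPKM2 library and by 1.34 with shikonin, and stood at 0.01 with TEPP-46. The highest values were 2926 FPKM for Spp1 among osteoblast markers, 261 FPKM for Tubb3 among neuronal markers, 28.8 FPKM for Krt19 among epithelial markers, 20.5 FPKM for Pparg among adipocyte markers and 1.62 FPKM for Egfl7 among endothelial markers. None of the 13 mitochondrially encoded transcripts of the list is in the table used here.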

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

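All tests of explanations in this part were chosen after the results were seen, and none has a replicate behind it.

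Some results went opposite ways with the compounds relative to the same vehicle library, and the difference was not tested because each condition has 1 library. Ccl2, a monocyte chemokine gene, was at 40.8 FPKM with shikonin and 3.57 FPKM with TEPP-46 against 13.5 FPKM with vehicle, a gap of 3.19 on the log2 scale. Myf5, a myogenic regulator gene, was at 3.69 FPKM with shikonin and 23.7 FPKM with TEPP-46 against 10.7 FPKM with vehicle, a gap of -2.39. The heat shock list was above the random range with shikonin and below it with TEPP-46, with a median gap of 1.11, and the proteasome list likewise, with a median gap of 1.02. The opposite directions depend on the vehicle library. In shControl, Ccl2 (359 FPKM) and Myf5 (32.1 FPKM) lay above their levels with both compounds. With TEPP-46 on shControl, the heat shock (-0.09) and proteasome (-0.17) lists did not stand apart.

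Interferon-stimulated genes were high in both hairpin libraries and low in the 3 libraries of 8 h. Immune cells among the myoblasts are argued against, since the highest of 8 leukocyte genes in the hairpin libraries was Csf1r at 0.111 FPKM, where Bst2 reached 574 FPKM. Markers outside these 8 were expressed. Cd68 stood at 12.9 FPKM in shPKM2 and 4.55 FPKM in shControl, but also at 7.89 FPKM with shikonin. Cd14 reached 26.7 FPKM in its highest library. Knockdown of Pkm was not needed for the pattern, since shControl, which carried a control hairpin, held it too. The list's median between shPKM2 and shControl was 0.0067 (quartiles -0.08 and 0.07). That value restates the pattern and is no separate test. The hairpin vector or its delivery, the 72 h in culture and a batch could each give the median of 4.16 between shControl and vehicle. They cannot be told apart, because they go together in every library.

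NRF2 targets were higher in shPKM2 than in shControl. Reads shared between Gsta copies are argued against as the whole source, since 25 of 29 members were higher (lower quartile 0.16). The 26 members without Gsta genes had a median of 0.46 (percentile 100). That value is no separate test, because leaving out so few members could not bring the median into the random range. Rescaling to TPM gave 0.55, which tests nothing about scaling because it shifts all genes of a library nearly alike. Whether shControl was low or shPKM2 high stays open. The list stood apart on the low side in shControl against vehicle (median -0.15, percentile 0.36). For shPKM2 against vehicle the median was 0.27 (percentile 99.99), and 18 of 29 members were higher in shPKM2 than in both controls. Vehicle belongs to another experiment, so these values do not decide it. An effect of lower Pkm may underlie the pattern, as may variation between cultures or an off-target effect of the hairpin, none of which was tested.

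G2/M genes were lower in the shikonin library. The median was -1.39 against shControl, and between shControl and vehicle it was -0.04 (percentile 30.2). A high level in the vehicle library alone is argued against only as far as the experiments can be compared, since shControl belongs to another one. Rescaling to TPM gave -1.49, which is no test of scaling because it shifts all genes of a library nearly alike. A general loss of short-lived transcripts stays open. Immediate early genes had a median of 0.27 (quartiles -0.29 and 0.78), with 20 higher and 13 lower. Levels alone do not separate decay from new transcription, so this list cannot decide the question. A response to shikonin is a candidate explanation as a hypothesis only, and variation between cultures stays open.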

How the results depend on the processing

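No paired analysis was possible because each condition has 1 library. All alternatives were fixed before the data were examined, except the counts and correlations without short RNA genes, which were added after seeing them, and all of them were run. Unless a reason is given, the cause was not tested. After rescaling to TPM the differences of Pkm were -0.92 in the knockdown, 0.12 with shikonin and -0.16 with TEPP-46. A pseudocount cannot turn the direction of a gene, and the scalings differed too little to turn a 2-fold difference. Of 170 list medians, the side of the random range was kept by 170 under a pseudocount of 0.1, 163 under a pseudocount of 5, 163 with no filter, 162 with unmatched random lists and 160 with a minimum mean of 5 FPKM. Median-of-ratios factors were so near 1 that this scaling is no check, and TPM, which kept 165, shifts all genes of a library nearly alike. Of these settings only the minimum of 5 FPKM turned a list, immediate early genes with TEPP-46, to 0.0946, since fewer of its genes entered. Differences of genes near 1 FPKM depend on the pseudocount by construction, since a pseudocount of 1 is as large as their values. Counting error is largest for low and short genes.

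Counts of genes moved with the pseudocount and the size limit by construction. With a pseudocount of 5, the genes higher were 28 in the knockdown, 244 with shikonin, 77 with TEPP-46, 220 between the compounds and 214 between the control libraries, and the genes lower were 16, 168, 20, 143 and 38. With a pseudocount of 0.1, the genes lower were 587 with shikonin, 90 with TEPP-46, 624 between the compounds and 129 between the control libraries. A limit of 1.5-fold gave 114, 1322, 383, 1220 and 903 higher and 91, 1496, 223, 1580 and 365 lower, in the same order. A limit of 3-fold gave 21, 129, 49, 109 and 191 higher and 13, 50, 14, 50 and 20 lower. A minimum mean of 5 FPKM left 28 higher in the knockdown, with fewer genes counted. After rescaling to TPM, 61 were lower with TEPP-46 and 124 between the control libraries. Without short RNA genes the knockdown had 25 higher and 12 lower, and TEPP-46 had 25 lower, with fewer genes counted.

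The choice of control library turned the most lists. It swaps in a library of another experiment, so the differences between the control libraries enter by construction. With vehicle as control, shPKM2 had 456 genes higher and 91 lower, and 11 of 34 lists turned: glycolysis to 0.61, serine, glycine and one-carbon to -0.22, TCA cycle to 0.15, oxidative phosphorylation to 0.16, unfolded protein response to 0.43, Wnt targets to 0.25, HIF1 targets to 0.62, ribosome biogenesis to -0.37, NF-kB and inflammatory genes to 1.08, apoptosis regulators to 0.23 and YAP targets to -0.87. With shControl as control, shikonin had 831 genes lower and TEPP-46 had 224 higher and 488 lower, and 12 of 68 list medians turned. With shikonin these were glycolysis (-0.59), ribosome biogenesis (0.29), NF-kB and inflammatory (-1.09) and interferon-stimulated genes (-3.99). With TEPP-46 they were unfolded protein response (-0.46), HIF1 (-0.56), interferon-stimulated (-4.21), autophagy (-0.44), extracellular matrix (0.25), TGF-beta (0.28), YAP (0.46) and SRF genes (0.24). The correlation of shikonin with TEPP-46 was 0.185 with shikonin on shControl and 0.0466 with TEPP-46 on shControl.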

Other observations

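The hairpin libraries and the 8 h libraries differed in more than interferon-stimulated genes. The chemokine genes Ccl5 (7.90, 614 FPKM against 1.57 FPKM), Ccl7 (5.48), Cxcl10 (5.09) and Ccl2 (4.63) were higher in shControl than in vehicle, while Cxcl12 was lower (-0.71), and 12 of 19 NF-kB and inflammatory genes were at least 2-fold higher (median 1.34, percentile 100). Sterol genes were higher as a group: 23 of 23 cholesterol biosynthesis genes, 8 of them at least 2-fold (median 0.87, percentile 100), with Insig1 at 1.94, the farnesyl diphosphate synthase gene Fdps at 1.49 and Idi1 at 1.40. Glycolysis genes had a median of 0.64 (percentile 100), with the lactate exporter gene Slc16a3 at 2.49, Pfkm at 1.12 and Aldoa at 1.04, and Pkm itself stood at 0.64. HIF1 targets stood at 0.66, with Bnip3 at 2.56, and unfolded protein response genes at 0.52. SRF and cytoskeleton genes had a median of -0.31, with 18 of 21 lower in shControl and 5 at least 2-fold lower: Tagln (transgelin) was at 4.99 FPKM against 121 FPKM (-4.35), Actg2 at -2.89, Acta2 at -2.62 and Myl9 at -2.31. YAP targets had a median of -0.75 with Cyr61 at -1.39, and ribosome biogenesis genes were lower in 29 of 30 cases (median -0.41). The RNA genes Rmrp (-1.47), Rpph1 (-1.05) and Rn45s (-0.71) and Lars2 (-0.91) were lower in shControl as well.

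In all, 15 lists stood above the random range and 8 below it between these controls, more than in the knockdown comparison, where 8 stood above and 7 below. The comparison joins the hairpin, the hours of culture and any batch, so none of these differences has a stated origin.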
